A study of Mus musculus with 63 samples.

How the data were processed

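Poly(A) RNA from single mouse livers was sequenced as single-end reads of 50 nucleotides on an Illumina HiSeq instrument. The 63 libraries came from 25 WT males, 26 KO males and 12 Het females, each from its own mouse, killed 0 to 14 days after the start of tamoxifen. The KO males carried a tamoxifen-inducible Cre under the albumin promoter together with a lox-flanked Hcfc1 allele on their only X chromosome. Het females carried the same Cre with 1 lox-flanked allele and 1 intact allele. The samples' protocol describes the WT males as lox-carrying mice without Cre, while their genotype label gives C57BL/6.

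Per the labels, the authors aligned the reads to the mm9 mouse genome with TopHat2 2.0.13 and Bowtie 1.1.2 and used edgeR to make the gene values. The deposited table holds log2 values of normalized read density (RPKM, reads scaled by exon length and library size) for 15616 genes. A constant of 8.9e-05 had been added before the logarithm, so that a gene with no reads stands at the table's minimum of -13.4557. Such genes are called listed at 0, and 5.02% of all values are. Low values were checked against whole reads: after removal of the constant, 99.3% of those of 725 weakly expressed genes lay within 0.02 reads of a whole number. Gene positions and exon lengths came from an mm9 annotation, to which 15041 genes (96.3%) were matched, 14300 of them by their own symbol. From the size of 1 read, the libraries were estimated to hold 18.3M to 58.6M reads, with a median of 37.7M. A single read over 2000 bp of exon corresponds to 0.0097 to 0.036 RPKM across the libraries. These limits cover counting error only. Summed read density per library, which is 1 for plain totals, ranged from 0.868 to 2.15, so the deposited values carry a scale that differs between libraries.

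Every comparison was tested with limma 3.58.1 (R 4.3.3), with eBayes and its intensity trend, on the deposited log2 values. The test planned for a table of raw counts was not used, since the table holds log2 values. Tested genes had a log2 value of at least 0 in at least 4 libraries (12221 genes in males, 12380 in all 63 libraries) or in at least 2 libraries (11919 genes in females). The 51 male libraries were fitted with 1 mean per genotype and day, leaving 21 residual degrees of freedom and a prior worth 5.62. Window contrasts are unweighted means over days of KO minus WT on the same day. Days 10 to 13 have 1 library per genotype, and day 14 has 1 WT and 2 KO libraries. The second of these is an unnumbered column named as KO of day 14, assumed to be replicate 2. Those lone libraries are assumed to vary like the replicated ones. The 12 female libraries, 1 per day, were fitted with 1 mean per window, leaving 8 residual degrees of freedom, so their spread includes change within a window. WT males over time were tested with limma's F test over 4 windows against day 0. Their fold changes, standard errors and directions, and the list tests, are those of days 10 to 14 against day 0, so a gene counted there passed over any window. No WT females were sequenced. Differences between females and males were fitted on all 63 libraries with 29 residual degrees of freedom. The p values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. All tests are two-sided.

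The median gene shifted between KO and WT males by up to 0.85 on the log2 scale over a window. Fold changes are therefore given relative to the median gene of the comparison, with the standard error and adjusted p of the deposited values. A gene is said to have risen or fallen only where it passed the threshold with 1 sign both in the deposited values and after each library was centred on its median. With the median gene shifted upward, this rule undercounts falls. The counts from each scale are given beside it. All numbers after ± are standard errors.

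The comparisons, windows, tests, filters, gene lists and rule for named genes were fixed before the data were examined. The fit after centring each library, and with it the rule for what rose or fell, was added after seeing the data. The rule for named genes takes Hcfc1. For KO against WT on days 3 to 5, 6 to 9 and 10 to 14 it takes the 10 largest rises and falls among genes past the threshold, with 1 sign on every day of the window and a mean of at least 1 RPKM in the higher genotype. For the other comparisons it takes the 5 largest each way without the every-day condition. In each list it takes up to 4 members with the smallest p among those past the threshold, or up to 2 as values where none passed. Where libraries of a group were listed at 0, mean levels are given and no fold.

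There were 32 lists, for liver metabolism, mitochondria, ribosomes, cell types, the cell cycle and stress responses. All but 1 were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The carry-over list for pancreas, adipose tissue and gallbladder had 13 of its 22 genes in the table and 1 tested gene, so it had no test. Members are counted over all genes tested and, separately, adjusted over the list alone. With the estimated correlation, list calls held in WT males over time (male-biased genes, P450s, unfolded protein response, erythrocytes). In Het females they held for P450s in all 3 windows, for secreted proteins, acute phase and female-biased genes on days 3 to 5 and 6 to 8, and for erythrocytes on days 3 to 5. For Het change minus KO change the call on female-biased genes held on days 6 to 8. No list call between KO and WT males held.

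Libraries carried serial numbers in 2 sets, treated as batches. The sets held 13 and 12 WT, 14 and 12 KO, and 12 and 0 Het libraries. Days 2 and 9 lie wholly in the later set, and days 10 to 14 and the females in the earlier one. Replicate numbers equalled the batch on 8 days. Correlations of KO and WT libraries with the same number ranged from -0.055 to 0.286 per day, with 4 days over 0.1, so pairing was used only as an alternative. A check of 3 Y-linked genes put every library on the side of its labelled sex: the highest female log2 value was -3.03 and the lowest male one 0.45. No 2 libraries were identical, and the highest correlation between libraries was 0.9925.

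The fits were tested on simulated data with 200 changed genes and noise drawn independently for each gene. Apart from day 0, limma called more genes than that in the real data. Simulated calls were counted after each library was centred on its median, so they do not describe the test on deposited values. Of genes changed by 1 on the log2 scale, limma recovered 79.1% on days 1 to 2, 85.1% on days 3 to 5, 91% on days 6 to 9, 85.1% on days 10 to 14, 49.3% on day 0, 68.7% in Het females on days 10 to 13 and 29.9% for Het change minus KO change. False calls numbered 3 to 9. Alternatives were quantile normalization, centring on the library median, scaling to library totals, 0.1 RPKM added before the logarithm, no filter, no intensity trend, batch as a covariate, a replicate block, windows fitted alone or shortened, a straight line in day, each library left out, estimated correlation, and limma's fry. Numerical work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.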

Results

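Gene expression was measured in the livers of 63 mice aged 10 to 14 weeks, killed in the morning 0 to 14 days after the first of 3 daily tamoxifen injections. HCF-1, the product of Hcfc1 (mm9, chromosome X, 71188131 to 71211696, minus strand), is a nuclear cofactor that joins DNA-bound transcription factors to chromatin-modifying enzymes. Livers in which Hcfc1 was to be deleted from hepatocytes were followed in 26 KO males against 25 WT males, and in 12 Het females, whose livers hold hepatocytes with and without an intact active allele if deletion took place, because the gene is X-linked. Deletion itself was not measured here. Per the samples' protocol the WT males carried no Cre. Effects of Cre and of Hcfc1 loss therefore cannot be told apart between KO and WT males. Days 0 to 9 had 2 libraries per male genotype, and days 10 to 14 had 1, apart from 2 KO libraries on day 14, the second of them an unnumbered column assumed to be replicate 2. Females had 1 library on each of 12 days. The libraries held an estimated 18.3M to 54.5M reads in WT, 22.1M to 58.6M in KO and 29.4M to 50.4M in Het mice. The series title names rapid steatohepatitis after loss of HCF-1, and the time course asks which liver genes changed, and when.

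**Figure D1:**
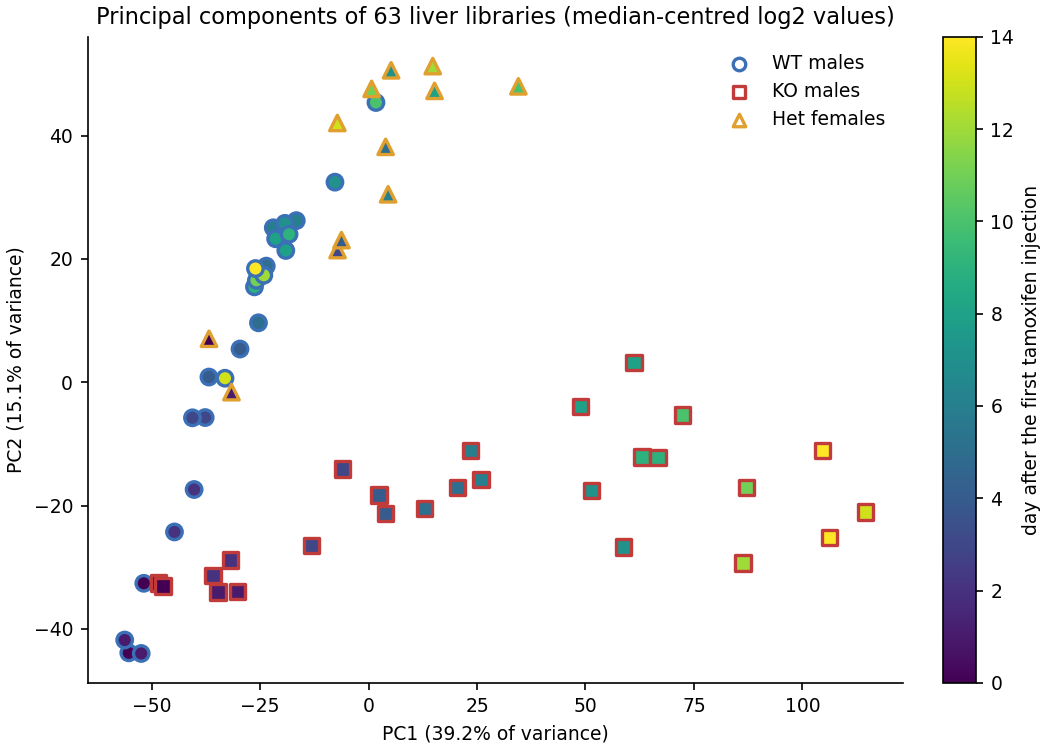
Libraries by their first 2 principal components over tested genes, one point per library, shaped by group and shaded by day. The components hold 39.2% and 15.1% of the variance, and KO livers of the late days lie away from the other livers.

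The median gene was higher in KO than in WT libraries by 0.09 on day 0, 0.23 on days 1 to 2, 0.33 on days 3 to 5, 0.23 on days 6 to 9 and 0.85 on days 10 to 14 on the log2 scale, and changes below are relative to it.

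**Figure D2:**
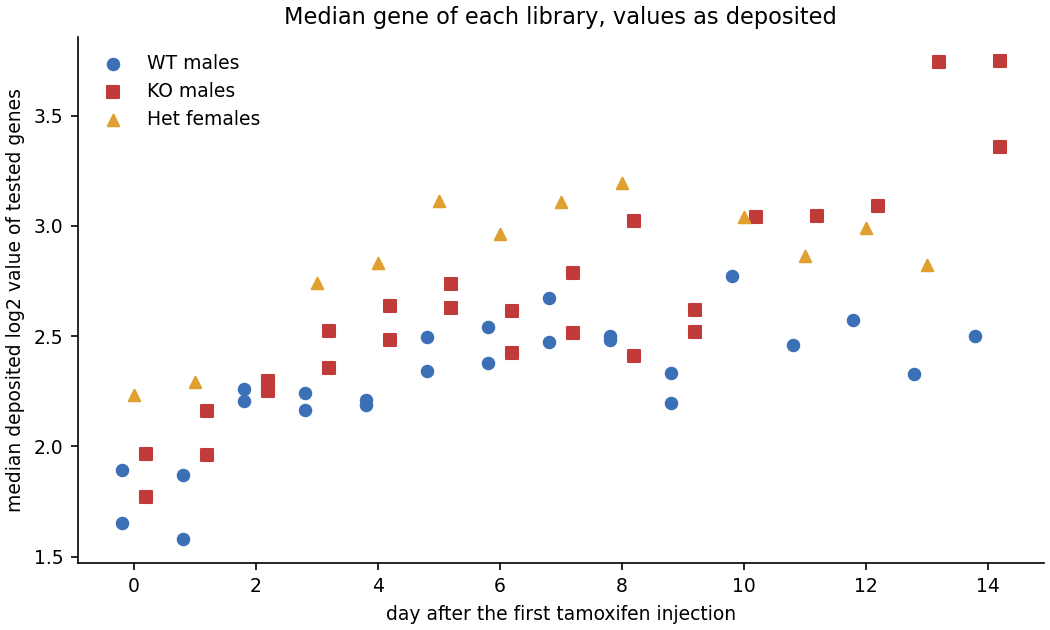
Median log2 value over tested genes in each library against day, as deposited, with one point per library and one colour per group. The KO libraries of days 13 and 14 stand above the WT libraries of the same days, where the median gene differs by 1.46 and 1.14.

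On day 0, the day of the first injection, few genes differed between the genotypes. Zbtb7c, a zinc finger gene, was higher in KO livers by 2.31 ± 0.41 (adjusted p = 0.00949), and Agpat9, a glycerol-phosphate acyltransferase, by 1.90 ± 0.28 (adjusted p = 0.00226). Dct, a melanin enzyme, was lower (-2.42 ± 0.38, adjusted p = 0.00949), as were Lrtm1 (-2.17 ± 0.40) and Arfgap3 (-1.47 ± 0.27). Foxa3, a hepatocyte transcription factor, differed by 1.29 ± 0.25 in the deposited values (adjusted p = 0.0183) and missed the threshold after centring (adjusted p = 0.0667). Hcfc1 differed by 0.16 ± 0.27 (adjusted p = 1.0). No member of any list passed the test over all genes. Adjusted over the list alone, 11 of 30 unfolded protein response genes were lower, and their list had a median of -0.49 (camera adjusted p = 6.31e-17, adjusted p = 0.133 with an estimated correlation). Their smallest p values belonged to Dnajb9 (-1.36 ± 0.26, adjusted p = 0.056) and Creld2 (-2.05 ± 0.49, adjusted p = 0.202). Adjusted over the list alone, 9 of 34 mitosis genes were higher, with a median of 0.77 (camera adjusted p = 6.4e-12, adjusted p = 0.535 with an estimated correlation). With 2 libraries per genotype, limma called 9 of 12221 genes, and 542 had an unadjusted p under 0.05. That count ranged from 4 without KO day 0 replicate 2 to 44 without WT day 0 replicate 1. With replicate pairs as blocks limma called 0, with 357 genes at an unadjusted p under 0.05, so each call named here was lost.

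Days 1 to 2 ask what changed during the injections. Alb, which encodes serum albumin, fell from a mean of 21700 RPKM in 4 WT livers to 1680 in 4 KO livers (-3.94 ± 0.42, adjusted p = 1.89e-06). The keratin Krt4 (-4.51 ± 0.50), the desmosomal cadherin Dsg1c (-4.37 ± 0.38), the retinol-oxidizing enzyme Adh7 (-3.73 ± 0.33) and the homeodomain gene Hopx (-3.31 ± 0.28) fell as well. Gldn rose by 4.03 ± 0.72, Dnaic1 by 2.68 ± 0.78, G6pdx, the first enzyme of the pentose phosphate pathway, by 2.64 ± 0.36, the surface protein gene Ly6d by 2.54 ± 0.36 and Fam81a by 2.47 ± 0.24. Hcfc1 itself was higher in KO livers by 0.46 ± 0.19 (adjusted p = 0.0162). Gene-level reads come from exons both inside and outside the lox-flanked part, so this value does not measure deletion.

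Among 24 cholesterol synthesis genes, 9 fell and 0 rose in that window (10 fell adjusted over the list alone), with a median of -0.62 (camera adjusted p = 5.2e-15, adjusted p = 0.235 with an estimated correlation). Sqle, the squalene epoxidase gene, and Nsdhl, a sterol dehydrogenase gene, fell (-0.98 ± 0.16 and -0.93 ± 0.17). Of 48 genes of the mitochondrial ribosome and mitochondrial translation, 12 rose and 0 fell (13 rose adjusted over the list alone), Mrpl11 by 0.58 ± 0.12 and Mrps18b by 0.44 ± 0.11 (camera adjusted p = 4.08e-06, adjusted p = 0.943 with an estimated correlation). Of 19 T, B and NK cell genes, 7 rose and 0 fell (10 rose adjusted over the list alone), among them Cd4 (2.15 ± 0.29, adjusted p = 4.0e-06), with camera adjusted p = 0.00267 and adjusted p = 0.884 with an estimated correlation. The list's median was 0.39 on day 0, 1.11 on day 1 and 0.32 on day 2, and on days 1 and 2 the medians were 1.15 and -0.03 for neutrophils and 0.86 and 0.06 for macrophages. Of 34 mitosis genes, 9 rose and 0 fell (18 and 1 adjusted over the list alone), including the kinase gene Plk1 (1.96 ± 0.44), and list medians of 0.77 on day 0, 0.90 on day 1 and 0.46 on day 2, with camera adjusted p = 8.3e-04 and adjusted p = 0.951 with an estimated correlation. In total 2253 of 12221 genes passed, 2029 higher and 224 lower. After centring 1113 were higher and 819 lower, and 1106 rose and 223 fell in both. The count was 886 without KO day 1 replicate 2 and 2946 without KO day 1 replicate 1, with 1061 without WT day 1 replicate 2, 1288 without WT day 2 replicate 1, 1334 without WT day 2 replicate 2 and 1094 without KO day 2 replicate 2. It was 1463 with replicate pairs as blocks, 1230 with the libraries of these days alone and 1435 after quantile normalization.

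Days 3 to 5 cover the first days after the injections, with 6 libraries per genotype. Every gene named by rank for this and the next 2 windows differed in 1 direction on each day of its window. Ly6d rose from 2.75 to 198 RPKM (5.80 ± 0.29, adjusted p = 2.71e-14). Plch2, a phospholipase C gene, rose by 4.83 ± 0.78, Ntrk2, which encodes a neurotrophin receptor, by 4.64 ± 0.55, the growth factor gene Nrg1 by 4.08 ± 0.41 and Stap1 by 4.06 ± 0.27. Tmc5, Wfdc15b and Pnpla5 averaged 1.40, 2.72 and 2.06 RPKM in KO livers against 0.08, 0.129 and 0.181 in WT livers, each listed at 0 in 1 of 6 WT libraries. Alb fell from 58000 to 4190 RPKM (-4.17 ± 0.34, adjusted p = 1.13e-09). Dsg1c (-5.67 ± 0.31), the steroid dehydrogenase gene Hsd3b5 (-4.92 ± 0.78), Krt4 (-4.89 ± 0.41), the synaptotagmin gene Syt3 (-4.63 ± 0.30), Plekhb1 (-4.49 ± 0.28), Camk2n2 (-4.39 ± 0.36), Hopx (-4.34 ± 0.23) and Adh7 (-4.18 ± 0.27) fell too. Hcfc1 stood at 15.6 RPKM in KO and 6.16 in WT livers (1.03 ± 0.16, adjusted p = 9.46e-08).

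**Figure D3:**
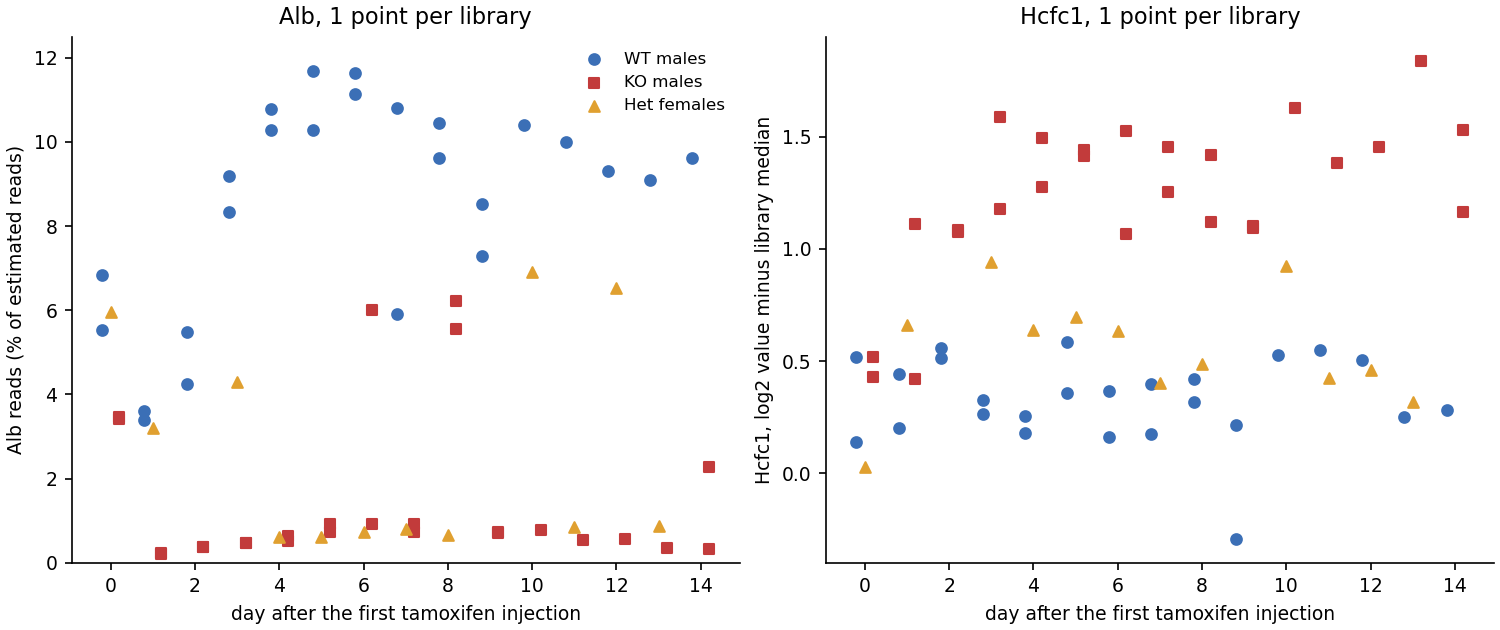
Share of reads taken by Alb (percent) and log2 level of Hcfc1 minus the library median in each library against day, one point per library. The Alb share spans 3.39 to 11.7% in the 25 WT libraries and 0.203 to 6.23% in the 24 KO libraries of days 1 to 14, of which 20 lie under 1%.

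Of 34 mitosis genes, 30 fell on days 3 to 5 and 0 rose, the same counts as adjusted over the list alone, with a median of -1.85 (camera adjusted p = 3.11e-24, adjusted p = 0.352 with an estimated correlation). The mitotic kinase genes Nek2 (-3.07 ± 0.27, 0.501 against 3.6 RPKM) and Aurka (-2.39 ± 0.31) and the spindle gene Prc1 (-2.38 ± 0.30) were among them. These falls are against WT livers of the same days, and in WT males over time mitosis genes were themselves higher than on day 0. KO livers were not tested against their own day 0, so a fall within KO livers is not shown. Of 32 DNA replication genes, 9 fell and 3 rose, also adjusted over the list alone, with falls of E2f2 (-2.23 ± 0.25) and E2f1 (-1.46 ± 0.17), which drive S phase entry, and a rise of the cyclin gene Ccnd1 (1.14 ± 0.15), with camera adjusted p = 1.67e-04 and adjusted p = 0.994 with an estimated correlation.

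Of 22 lipogenesis genes, 13 rose on days 3 to 5 and 0 fell (15 and 1 adjusted over the list alone), including Acly, which makes acetyl-CoA from citrate (2.09 ± 0.26), and the desaturase gene Fads2 (1.29 ± 0.24), though the list test gave camera adjusted p = 0.113. Of 32 genes of the NRF2 and oxidative stress response, 13 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0919), with Nqo1 at 27.7 against 5.41 RPKM (1.98 ± 0.18), Ugdh (1.28 ± 0.14) and G6pdx (2.89 ± 0.30). Drug-metabolising P450 and conjugation genes went both ways, with 11 of 27 up and 6 down (12 and 6 adjusted over the list alone), with Ugt2b1 (-3.97 ± 0.24) and Cyp2j5 (-3.45 ± 0.28) down (camera adjusted p = 0.455). Bile acid genes split 8 up and 6 down of 25, also adjusted over the list alone, with the conjugating enzyme Baat down (-1.57 ± 0.10) and Cyp8b1, the sterol 12-alpha-hydroxylase, up (0.90 ± 0.18); the list's median was 0.06 and its mean -0.22 (camera adjusted p = 0.422). Of the 35 secreted hepatocyte proteins, 9 rose and 4 fell, also adjusted over the list alone, with Alb low and the coagulation factor gene F12 (0.62 ± 0.08) high (median 0.05, mean -0.13, camera adjusted p = 0.859).

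Mitochondrial genes split by member on days 3 to 5. Of 48 mitochondrial ribosome and translation genes, 20 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 3.02e-04, adjusted p = 0.994 with an estimated correlation), with Mrps18b up by 1.37 ± 0.09 and Mrpl11 by 1.33 ± 0.10. Ndufa3, a subunit of respiratory complex I (chromosome 7, 3568975 to 3571765), fell from 111 to 34.8 RPKM (-2.35 ± 0.16, adjusted p = 1.3e-10), in a list where 5 of 54 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.928). Etfdh, which passes electrons from fatty acid oxidation to the respiratory chain, stood at 46.5 against 104 RPKM, while 9 of the 33 genes of its list rose and 5 fell, also adjusted over the list alone (median 0.09, mean -0.18, camera adjusted p = 0.913). Of 18 genes for HCF-1 and its partners, 10 rose and 1 fell, also adjusted over the list alone, with Yy1 up by 0.92 ± 0.10 (camera adjusted p = 0.0446, adjusted p = 0.994 with an estimated correlation). Of 20 clock genes, 11 rose and 1 fell (13 and 1 adjusted over the list alone), Dbp by 3.70 ± 0.56 (camera adjusted p = 0.455). Of 28 endothelial genes, 0 passed on both scales over all genes or adjusted over the list alone; 14 were lower after centring and the list's median was -0.37 (camera adjusted p = 0.0399, adjusted p = 0.994 with an estimated correlation). Duct cell genes had 11 of 23 up and 0 down (10 up adjusted over the list alone; median 0.67, camera adjusted p = 0.113), macrophage genes 10 of 35 up and 0 down, also adjusted over the list alone (median 0.35, camera adjusted p = 0.125), and neutrophil genes 3 of 12 up and 0 down (0 adjusted over the list alone; median 0.72, camera adjusted p = 0.859). Over all genes 6971 passed, 5797 higher and 1174 lower. After centring 3236 were higher and 2989 lower, and 3236 rose and 1174 fell in both. Within batch 1 limma called 3269 genes and within batch 2 5679.

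Days 6 to 9 ask how the difference stood in the following days, with 8 libraries per genotype. Bhlha15, a transcription factor gene of secretory cells, rose from 0.0896 to 6.85 RPKM (6.12 ± 0.32, adjusted p = 7.66e-15). Tinag, Sprr1a, Spink3 and Popdc3 averaged 2.68, 7.13, 2.2 and 1.65 RPKM in KO livers, and were listed at 0 in 5, 4, 4 and 2 of 8 WT libraries. Gpnmb, a glycoprotein gene of lipid-laden macrophages, averaged 2.92 against 0.0527 RPKM, listed at 0 in 1 WT library. Mmachc, which processes vitamin B12 (chromosome 4, 116374884 to 116381011), fell from 8.21 to 0.342 RPKM (-4.95 ± 0.21, adjusted p = 5.29e-16). Plekhb1 (-5.39 ± 0.24), the uncharacterised gene 0610011F06Rik (-5.19 ± 0.17), the cytokine gene Ctf1 (-4.87 ± 0.34), Syt3 (-4.77 ± 0.26), Mypop (-4.22 ± 0.26), Tmem102 (-4.21 ± 0.25) and Clpb, a mitochondrial disaggregase gene (-4.16 ± 0.18), fell as well. Cox7a1 was at 0.391 against 2.69 RPKM and listed at 0 in 1 of 8 KO libraries. Hcfc1 was higher by 0.97 ± 0.14 (adjusted p = 3.09e-08).

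On days 6 to 9, of 54 oxidative phosphorylation genes, 19 fell and 5 rose (19 and 4 adjusted over the list alone; camera adjusted p = 0.00209, adjusted p = 0.894 with an estimated correlation). Ndufa3 fell from 123 to 11.5 RPKM (-3.66 ± 0.14), and the ATP synthase gene Atp5d (-2.78 ± 0.12) and Cox7c (-1.72 ± 0.10) fell too. Cytosolic ribosomal proteins had 19 of 41 down and 3 up (20 and 3 adjusted over the list alone), including Rplp1 (-2.03 ± 0.11) and Rpl12 (-1.32 ± 0.10), with camera adjusted p = 2.77e-04 and adjusted p = 0.894 with an estimated correlation. In the mitochondrial ribosome list 20 of 48 rose and 7 fell, also adjusted over the list alone; Mrps18b was up (1.80 ± 0.07) and Mrpl24 down (-2.62 ± 0.12), with camera adjusted p = 0.176. Fatty acid oxidation genes had 12 of 33 down and 6 up, also adjusted over the list alone (camera adjusted p = 0.0444, adjusted p = 0.894 with an estimated correlation). Etfdh fell (-2.34 ± 0.11), while the fasting hormone gene Fgf21 rose from 0.341 to 4.8 RPKM (3.96 ± 0.48).

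Of 41 stellate cell and matrix genes, 36 rose in the same window and 0 fell, such as Col4a1 (0.98 ± 0.15), Lum (0.75 ± 0.13) and Tgfb2 (2.01 ± 0.30), with camera adjusted p = 4.95e-05 and adjusted p = 0.805 with an estimated correlation. Of 32 NRF2 genes, 23 rose and 0 fell, among them Srxn1 (1.84 ± 0.13) and Sqstm1 (1.27 ± 0.10), with camera adjusted p = 4.95e-05 and adjusted p = 0.786 with an estimated correlation. Of 30 p53 target and apoptosis genes, 21 rose and 0 fell, among them Gadd45a (1.55 ± 0.17). Of 30 unfolded protein and integrated stress response genes, 21 rose and 1 fell, with Atf3 up by 2.49 ± 0.19 and Ddit3, which encodes CHOP, by 2.04 ± 0.20. Of 23 duct cell genes, 17 rose and 0 fell, with Krt8 up by 1.55 ± 0.11, Elf3 by 2.22 ± 0.18 and Sox9 by 1.76 ± 0.16. Immediate early and heat shock genes had 17 of 22 up and 1 down, Jun by 2.11 ± 0.21, and fetal liver genes 12 of 16 up and 2 down, with Afp, alpha-fetoprotein, up by 1.57 ± 0.19. On day 6 the medians were 0.03 for fetal and 0.21 for duct cell genes. On days 7 to 9 they were 1.22, 0.86 and 1.40 for fetal and 1.52, 0.79 and 1.38 for duct cell genes. Stellate cell and matrix genes had medians of 0.264 on day 0, 0.226 on day 6 and 0.874, 0.685 and 1.092 on days 7 to 9. Unfolded protein genes had 0.224 on day 6 and 1.119, 0.368 and 0.288 on days 7 to 9. Camera gave adjusted p = 3.54e-04 for p53 targets, 0.00102 for the unfolded protein response, 0.00125 for duct cells, 0.003 for immediate early genes and 0.0147 for fetal genes, each with adjusted p = 0.786 with an estimated correlation. Adjusted over the list alone, 22 p53 targets and 13 fetal genes rose, and the other counts here were the same. Among 35 macrophage genes, 13 rose and 1 fell (12 and 1 adjusted over the list alone), with the chemokine gene Ccl2 at 40.8 against 1.61 RPKM (3.76 ± 0.25) and Cd14 at 1.91 ± 0.13 (camera adjusted p = 0.0895).

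Mitosis genes on days 6 to 9 had 21 of 34 down and 0 up (camera adjusted p = 1.05e-05, adjusted p = 0.786 with an estimated correlation). Nek2 was down (-1.99 ± 0.23), and per day the list's median ranged from -2.03 on day 6 to 0.70 on day 8. Here too the rise of mitosis genes in WT males over time enters the difference. DNA replication had 9 of 32 down and 4 up (camera adjusted p = 0.0294, adjusted p = 0.894 with an estimated correlation), and Prim1, a primase subunit, was down (-2.26 ± 0.21). Amino acid catabolism had 13 of 29 down and 2 up (camera adjusted p = 0.00209, adjusted p = 0.894 with an estimated correlation), with the serine dehydratase gene Sds (-2.28 ± 0.24) and Asl of the urea cycle (-1.22 ± 0.13). Female-biased genes had 6 of 16 down and 1 up (camera adjusted p = 0.042, adjusted p = 0.786 with an estimated correlation), with Cyp4a10 at -2.16 ± 0.26. All 4 pairs of counts were the same adjusted over the list alone. In total 7657 genes passed, 5356 higher and 2301 lower. After centring 4285 were higher and 3657 lower, and 4285 rose and 2301 fell in both. Batch 1 alone called 3024 genes and batch 2 alone 6291.

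**Figure D4:**
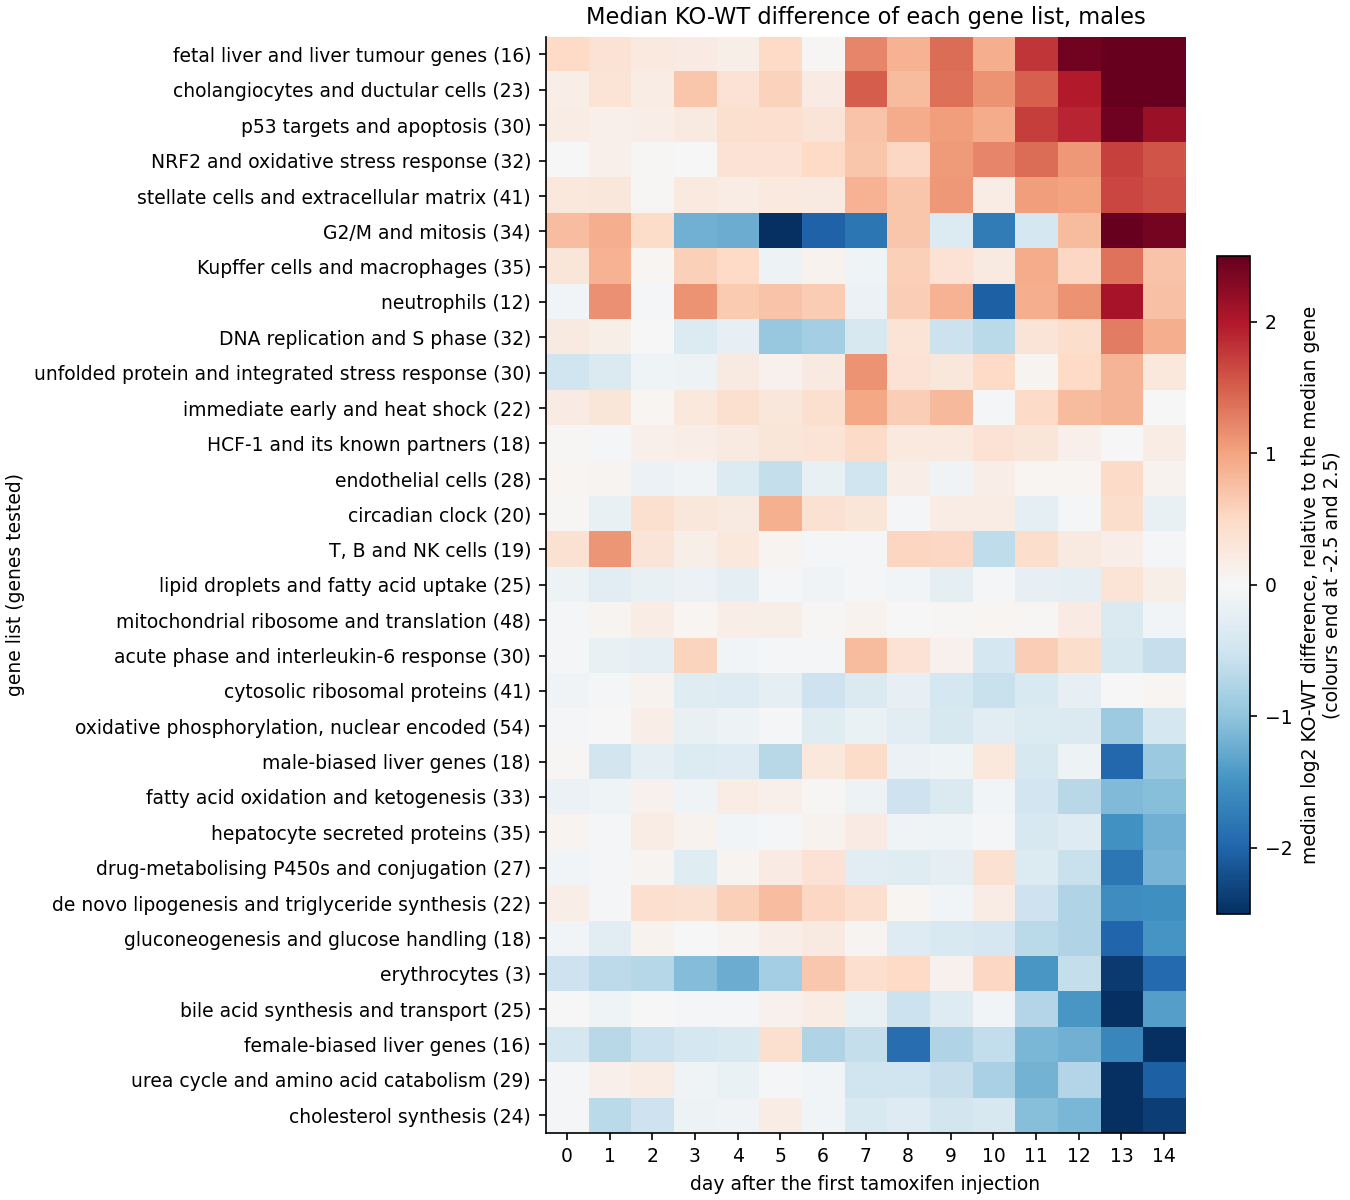
Heat map of the median relative log2 difference between KO and WT males for 31 gene lists, one line per list and one column per day from 0 to 14. Mitosis genes go from -3.06 on day 5 to 2.91 on day 13, and cholesterol synthesis genes reach -2.62 on day 13.

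Days 10 to 14 are the last stretch, with 6 KO and 5 WT libraries. Ly6k, Fosl1, Apela, Tinag and Areg, an EGF family growth factor gene, averaged 5.61, 9.5, 2.19, 7.94 and 26.2 RPKM in KO livers, and were listed at 0 in 4, 4, 4, 3 and 3 of 5 WT libraries. The histone genes Hist1h3d, Hist1h1a and Hist1h3e averaged 3.23, 1.8 and 1.54 RPKM and were each listed at 0 in 4 of 5 WT libraries. Sult3a1, a sulfotransferase gene, was at 0.231 RPKM in KO against 20.9 in WT livers, listed at 0 in 2 of 6 KO libraries. In WT males over time Sult3a1 was itself among the 5 largest rises (limma's F test, adjusted p = 3.81e-05). Its WT level had therefore risen since day 0, and that rise enters this difference. Nat1, an arylamine acetyltransferase gene, and Lcn12, a lipocalin gene, were each listed at 0 in 3 of 6 KO libraries, with WT means of 1.15 and 2.11 RPKM. Upp2, a uridine phosphorylase gene, fell from 103 to 5.45 RPKM (-6.01 ± 0.34, adjusted p = 2.22e-13), and C730036E19Rik (-6.35 ± 0.37), Krt4 (-6.09 ± 0.43) and 0610011F06Rik (-5.70 ± 0.21) fell too. Hcfc1 was at 30 against 7.83 RPKM (1.03 ± 0.17).

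In 6 metabolic lists more genes fell than rose in this window. Of 24 cholesterol synthesis genes, 17 fell and 0 rose, among them the sterol reductase gene Tm7sf2 (66.8 to 7.61 RPKM; -4.18 ± 0.15) and Idi1 (-2.57 ± 0.16), with camera adjusted p = 1.93e-13 and adjusted p = 0.259 with an estimated correlation. Of 29 urea cycle and amino acid genes, 19 fell and 1 rose, with Bhmt, the betaine methyltransferase, down from 1900 to 307 RPKM (-3.88 ± 0.16), and Otc (-2.80 ± 0.12) and Hal (-4.29 ± 0.26) down (camera adjusted p = 1.38e-13, adjusted p = 0.259 with an estimated correlation). Bile acid genes had 13 of 25 down and 4 up, with the uptake transporter gene Slc10a1 (-3.15 ± 0.12), Baat (-3.24 ± 0.11) and Cyp8b1 (-3.67 ± 0.19) down and the efflux pump gene Abcc4 up (4.33 ± 0.31), with camera adjusted p = 6.43e-08 and adjusted p = 0.246 with an estimated correlation. Gluconeogenesis genes had 8 of 18 down and 2 up, including Slc37a4, the glucose-6-phosphate transporter gene (-2.11 ± 0.14), with camera adjusted p = 5.49e-05 and adjusted p = 0.246 with an estimated correlation. Lipogenesis had 7 of 22 down and 2 up, with Thrsp (-4.24 ± 0.39) and the triglyceride-forming enzyme gene Dgat1 (-2.87 ± 0.13), with camera adjusted p = 2.45e-04. Fatty acid oxidation had 11 of 33 down and 4 up, with Acaa1a at -2.09 ± 0.10 (camera adjusted p = 4.38e-04), and both had adjusted p = 0.588 with an estimated correlation. On day 10 the medians were 0.18 for lipogenesis, -0.08 for fatty acid oxidation and -0.065 for bile acid genes. On day 13 they were -1.56, -1.11 and -2.626. These 6 lists had the same counts adjusted over the list alone.

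Lipid storage genes moved apart. Cidec, which enlarges lipid droplets, rose from 0.14 to 50.1 RPKM (6.44 ± 0.53, adjusted p = 1.8e-12) and the lipase gene Lpl rose by 1.94 ± 0.22, while the fatty acid transporter gene Slc27a4 fell (-2.23 ± 0.11). In that list 12 of 25 rose and 8 fell, also adjusted over the list alone. Its median of 0.01 and mean of 0.20 are above 0, while camera points down (adjusted p = 0.0328, adjusted p = 0.588 with an estimated correlation). Of 35 secreted proteins, 11 fell and 2 rose (9 and 2 adjusted over the list alone), and Alb stood at 7580 against 61200 RPKM (-4.39 ± 0.37), with camera adjusted p = 2.64e-04 and adjusted p = 0.56 with an estimated correlation. Of 54 oxidative phosphorylation genes, 9 fell and 2 rose, also adjusted over the list alone, and 34 were lower after centring, with Atp5d (-3.53 ± 0.15) and Ndufa3 (-3.64 ± 0.17) down (camera adjusted p = 0.0328, adjusted p = 0.837 with an estimated correlation). P450 and conjugation genes had 8 of 27 up and 9 down, also adjusted over the list alone, with Cyp2a5 at 4360 against 75.0 RPKM (4.64 ± 0.31) and Cyp2c54 at -3.27 ± 0.15 (camera adjusted p = 0.00826, adjusted p = 0.588 with an estimated correlation). Male-biased genes had 5 of 18 down and 3 up (camera adjusted p = 0.00887, adjusted p = 0.588 with an estimated correlation), and female-biased genes 6 of 16 down and 2 up (camera adjusted p = 8.1e-04, adjusted p = 0.263 with an estimated correlation), the same counts as adjusted over the list alone. After centring the calls on male-biased (adjusted p = 0.131), female-biased (0.315), P450 (0.149) and lipid droplet genes (0.498) were lost, as they were after quantile normalization (0.168, 0.238, 0.458 and 0.538). Quantile normalization also ended the call on secreted proteins, and that on oxidative phosphorylation was lost without the filter. On day 10 the medians of male-biased and P450 genes were 0.26 and 0.37. For secreted proteins the median was -0.056 on day 10 and -1.517 on day 13. The steroid hydroxylase gene Cyp17a1 fell (-3.22 ± 0.26) and Cyp2a4 rose by 4.16 ± 0.31.

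Of 30 p53 targets, 25 rose in this window and 0 fell, such as the cell cycle inhibitor gene Cdkn1a (7.87 to 126 RPKM; 3.05 ± 0.23), Phlda3 (4.76 ± 0.31) and Bax (1.94 ± 0.12), with camera adjusted p = 1.15e-04 and adjusted p = 0.56 with an estimated correlation. Of 32 NRF2 genes, 22 rose and 0 fell (23 rose adjusted over the list alone), with Srxn1 up from 15 to 402 RPKM (3.53 ± 0.17) and Cbr3 by 5.34 ± 0.32 (camera adjusted p = 6.07e-05, adjusted p = 0.56 with an estimated correlation). Unfolded protein and integrated stress genes had 14 of 30 up and 1 down, with Psat1 (4.16 ± 0.26), Atf3 (3.73 ± 0.23) and Ddit3 (3.60 ± 0.24), with camera adjusted p = 0.0328 and adjusted p = 0.692 with an estimated correlation. Stellate cell and matrix genes had 38 of 41 up and 0 down, with Lum (1.44 ± 0.15) and Tgfb2 (3.71 ± 0.36), with camera adjusted p = 3.85e-04 and adjusted p = 0.588 with an estimated correlation. Duct cell genes had 18 of 23 up and 0 down, with Krt8 at 1330 against 79.5 RPKM (2.84 ± 0.13), Sox9 (2.12 ± 0.20) and Prom1, which the female-biased list also holds (4.52 ± 0.31), with camera adjusted p = 0.00462 and adjusted p = 0.588 with an estimated correlation. Macrophage genes had 25 of 35 up and 0 down, with Cd14 (2.88 ± 0.16) and Lgals3 (2.62 ± 0.24), with camera adjusted p = 0.0328 and adjusted p = 0.836 with an estimated correlation. The lists without a stated difference had the same counts adjusted over the list alone.

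The other lists did not pass as a whole in the deposited values, although members did. Fetal liver genes had 12 of 16 up and 0 down, Afp from 1.4 to 54.3 RPKM (3.46 ± 0.23), with camera adjusted p = 0.0722, and passed after centring (camera adjusted p = 0.00104), as they did after quantile normalization (0.00199) and without the filter (0.0474). Mitosis genes had 21 of 34 up and 0 down (20 up adjusted over the list alone; camera adjusted p = 0.459, and 0.0309 after centring), with Kif23 at 1.69 ± 0.31 and list medians of -1.75 on day 10, -0.43 on day 11, 0.79 on day 12, 2.91 on day 13 and 2.40 on day 14, and DNA replication 19 of 32 up and 1 down (camera adjusted p = 0.443), with Ccnd1 at 1.51 ± 0.16. Of 28 endothelial genes, 12 rose and 0 fell (10 adjusted over the list alone; camera adjusted p = 0.249). Immediate early genes had 10 of 22 up and 1 down, with Myc at 3.07 ± 0.32 (camera adjusted p = 0.406). The HCF-1 list had 9 of 18 up and 1 down (camera adjusted p = 0.14). Acute phase genes had 7 of 30 up and 6 down, with Orm3 at 4.35 ± 0.54 and Crp at -3.25 ± 0.16 (median 0.02, mean -0.04, camera pointing down with camera adjusted p = 0.0722). T, B and NK cell genes had 4 of 19 up (2 adjusted over the list alone; median -0.03, mean 0.09, camera adjusted p = 0.406), and erythrocyte genes 1 up and 2 down of 3 (camera adjusted p = 0.244). In 4 of these lists camera's direction opposed both the median and the mean, namely mitochondrial ribosome (18 of 48 up, 6 down, median -0.08, camera adjusted p = 0.237), cytosolic ribosome (9 of 41 up, 4 down, 8 and 4 adjusted over the list alone, median -0.25, camera adjusted p = 0.237), clock (7 of 20 up, 1 down, median 0.08, camera adjusted p = 0.705) and neutrophils (3 of 12 up, 0 down, median 0.76, camera adjusted p = 0.561). Where no other number is given, the counts were the same adjusted over the list alone.

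Of 12221 genes, 10122 passed on days 10 to 14, 8769 higher and 1353 lower. After centring 4714 were higher and 4090 lower, and 4714 rose and 1353 fell in both. All libraries of these days belong to batch 1. Across the last 3 windows, 1767 genes rose and 477 fell in each. Of the genes that rose on days 3 to 5, 2420 rose on days 6 to 9 (1135 by chance), and 893 fell in both (221 by chance). From days 6 to 9 to days 10 to 14 these overlaps were 3252 (1653 by chance) and 1041 (254.7 by chance). Day by day, limma called 9 genes on day 0, 1328 on day 1, 447 on day 2 and 5050 on day 9, and 11, 648, 1083 and 5233 after centring. Days 10 to 13 set 1 library against 1, assumed to vary like the others, with 2263 genes on day 10 and 9358 on day 13, and 2992 and 6463 after centring. Cyp8b1 differed by 1.20 on day 4 and -6.52 on day 13, Mmachc by -1.94 on day 3 and -4.62 on day 5, and Afp by -1.39 on day 4 and 5.83 on day 13.

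**Figure D5:**
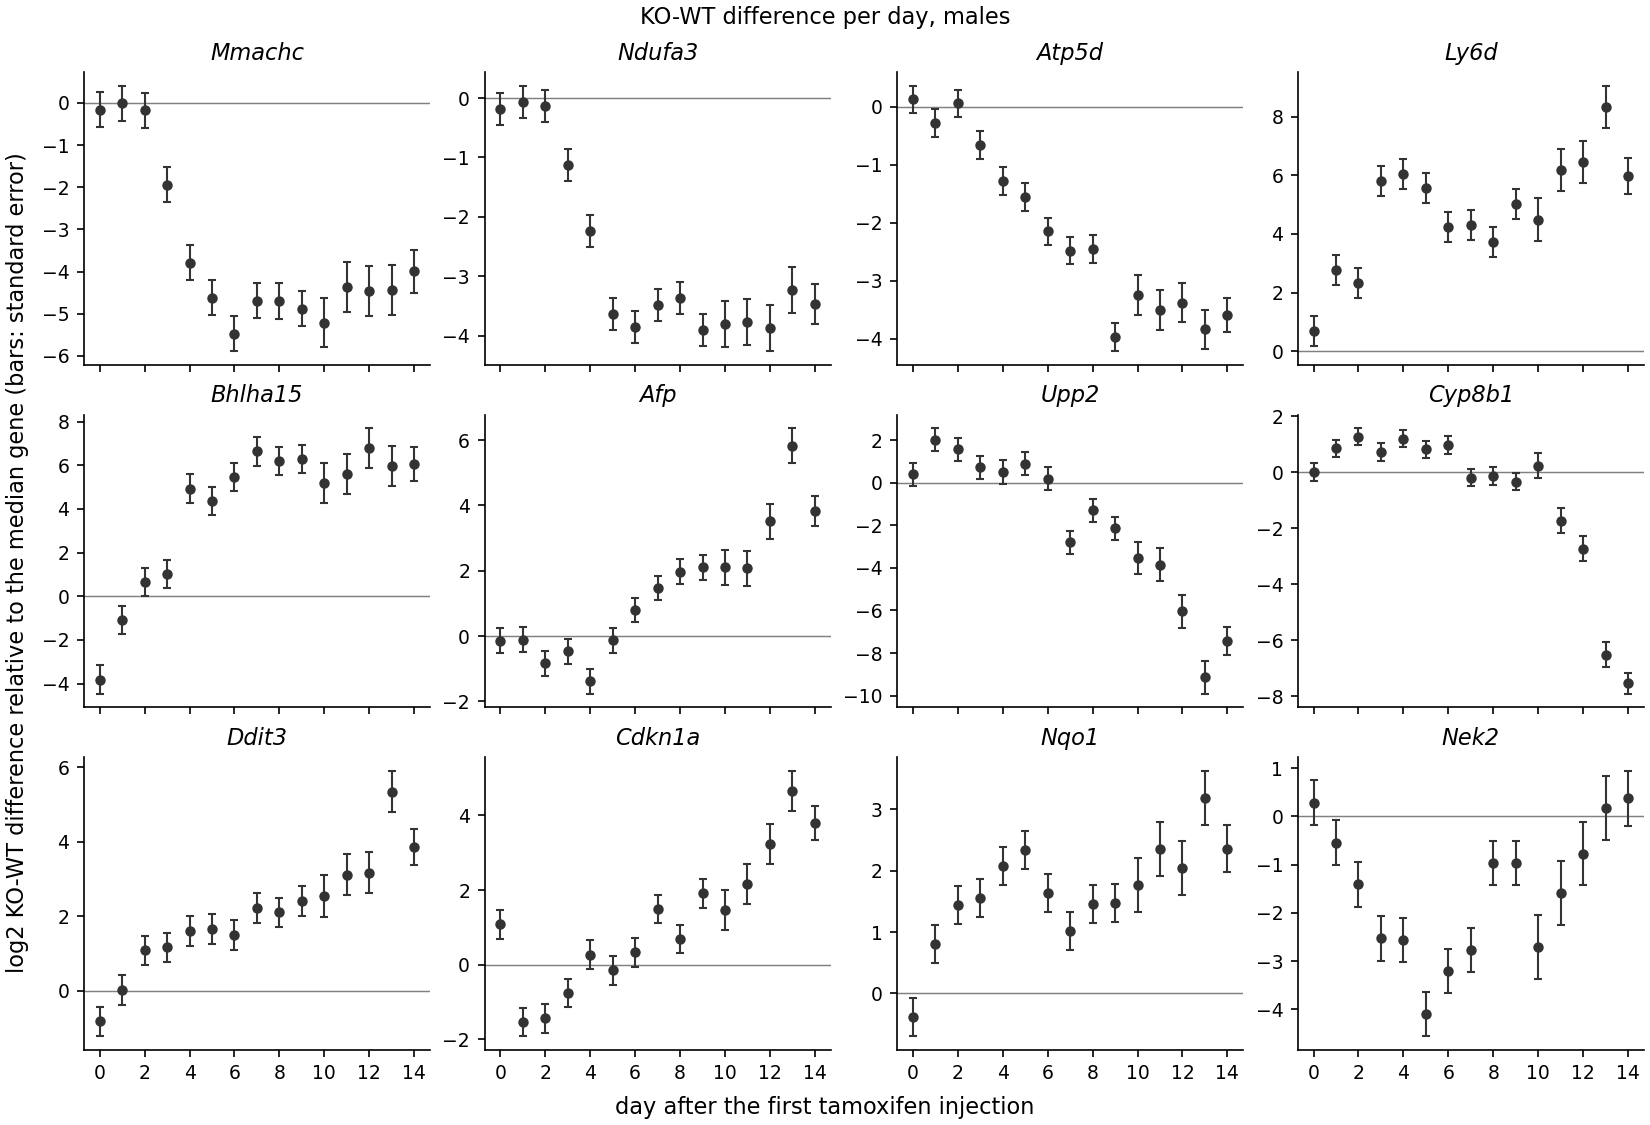
Relative log2 difference between KO and WT males on each day for single genes, with standard errors as bars. Mmachc and Ndufa3 lie near 0 until day 2 (-0.18 and -0.13) and at -5.47 and -3.85 on day 6, while Afp passes 2 on day 9.

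The change of the KO-WT difference between days 3 to 5 and days 10 to 14 tests directly whether effects grew or turned. Upp2, at 144 RPKM in early KO livers and 5.45 in late ones, changed by -6.71 ± 0.46 (adjusted p = 4.12e-11), and Plch2 by -7.38 ± 1.14. Arhgap36 went from 0.0138 to 1.17 RPKM in KO livers, listed at 0 in 2 of 6 early KO libraries, and Lcn12 from 0.45 to 0.141, listed at 0 in 3 of 6 late ones. Mitosis genes, whose median was still -1.75 on day 10 and above 0 on days 12 to 14, had 33 of 34 up and 0 down, a median of 2.62, and Ckap2 (3.79 ± 0.45) and Prc1 (3.44 ± 0.44) as examples (camera adjusted p = 4.21e-08, adjusted p = 0.496 with an estimated correlation). Changes with time in WT livers enter these values as well as changes in KO livers. DNA replication followed with 24 of 32 up and 0 down (camera adjusted p = 0.00356, adjusted p = 0.618 with an estimated correlation). Cholesterol synthesis had 17 of 24 down and 0 up (18 down adjusted over the list alone), a median of -1.5 and Fdps at -3.15 ± 0.27 (camera adjusted p = 9.63e-15, adjusted p = 0.253 with an estimated correlation). Lipogenesis had 12 of 22 down and 1 up, with Acly at -2.79 ± 0.38 and Dgat1 at -2.84 ± 0.18 (camera adjusted p = 4.21e-08, adjusted p = 0.403 with an estimated correlation). NRF2 genes had 17 of 32 up and 0 down, with Gsta1, a glutathione transferase gene, at 7.21 ± 0.67 (camera adjusted p = 6.63e-05, adjusted p = 0.496 with an estimated correlation). The counts were the same adjusted over the list alone except for cholesterol synthesis. Of 12221 genes, 7449 passed, 6149 higher and 1300 lower. After centring 3439 were higher and 3370 lower, and 3439 rose and 1300 fell in both. With genotype labels swapped within days, 12 of 100 splits, the real one included, called at least 7449 genes. Chance is therefore not excluded by this count. After centring, 3 of the 100 splits reached the real count.

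The change between day 0 and days 6 to 9 subtracts the difference of day 0. It gave -5.21 ± 0.39 for 0610011F06Rik (adjusted p = 1.63e-09) and -4.84 ± 0.54 for Plekhb1. Unfolded protein response genes had 18 of 30 up and 0 down (20 up adjusted over the list alone), with Creld2 (3.81 ± 0.55) and the chaperone gene Hspa5 (2.39 ± 0.38), with camera adjusted p = 1.89e-09 and adjusted p = 0.828 with an estimated correlation. Mitosis genes had 16 of 34 down and 0 up (19 down adjusted over the list alone), with Ccnb1 at -3.32 ± 0.71 (camera adjusted p = 1.07e-10, adjusted p = 0.828 with an estimated correlation). The day 0 difference, from 2 libraries per genotype, adds to both changes. On that day the list medians were -0.492 for unfolded protein and 0.772 for mitosis genes. The same WT libraries of day 0 serve in the comparison of WT males over time. Oxidative phosphorylation had 11 of 54 down and 0 up (9 down adjusted over the list alone), with Ndufa3 at -3.45 ± 0.31 and Atp5d at -2.87 ± 0.27 (camera adjusted p = 0.00904, adjusted p = 0.973 with an estimated correlation). Of 12221 genes, 2436 passed, 1430 higher and 1006 lower. After centring 1931 were higher and 1818 lower, and 1362 rose and 1003 fell in both. The count was 1407 without KO day 0 replicate 2.

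WT males were compared over time with their own livers of day 0, and no test separates tamoxifen from other changes with time. The female-biased gene Cyp2b9 rose from 0.0676 RPKM in 2 day 0 livers to 111 in 5 livers of days 10 to 14 (10.58 ± 2.33, adjusted p = 0.000226 for that window). Oxtr, the oxytocin receptor gene, averaged 3.41 RPKM late and was listed at 0 in both day 0 libraries. Male-biased Hsd3b5 fell from 134 to 7.08 RPKM (-6.09 ± 1.13), Cyp4a12b fell (-5.74 ± 0.67) and Elovl3 from 393 to 23.3 RPKM (-5.64 ± 0.69), and Moxd1 went from 19.4 to 0.0115 RPKM, listed at 0 in 2 of 5 late libraries. Counts here are of genes past limma's F test over any window, by their direction on days 10 to 14. Of 18 male-biased genes, 11 were lower and 0 higher (8 lower adjusted over the list alone), with camera adjusted p = 1.58e-27 and adjusted p = 0.0041 with an estimated correlation. Of 16 female-biased genes, 12 were higher and 1 lower (12 and 0 adjusted over the list alone), with Cux2 at 5.37 ± 0.77 (camera adjusted p = 0.0219, adjusted p = 0.491 with an estimated correlation). Macrophage genes had 34 of 35 up and 0 down (33 up adjusted over the list alone), with Cd14 (2.29 ± 0.22) and the complement gene C1qc (1.90 ± 0.27), with camera adjusted p = 1.77e-11 and adjusted p = 0.371 with an estimated correlation. Mitosis genes had 34 of 34 up (33 adjusted over the list alone), with Mki67 from 0.0667 to 1.64 RPKM (3.06 ± 0.41), with camera adjusted p = 1.39e-10 and adjusted p = 0.434 with an estimated correlation. Unfolded protein genes had 11 of 30 down and 4 up (7 and 3 adjusted over the list alone; camera adjusted p = 4.31e-18, adjusted p = 0.0293 with an estimated correlation), with Creld2 at -2.80 ± 0.41. P450 genes had 11 of 27 down and 3 up (3 and 2 adjusted over the list alone; camera adjusted p = 8.35e-14, adjusted p = 0.0293 with an estimated correlation). Over any window 10093 of 12221 genes passed, 9837 higher and 256 lower. After centring 2962 were higher and 3035 lower, and 2960 were higher and 250 lower in both. The median gene rose by 0.70 from day 0 to days 10 to 14, and all windows share the 2 day 0 libraries.

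Het females were compared with their own 2 livers of days 0 and 1, which asks how livers labelled Het changed. On days 3 to 5, in 3 livers, A1bg fell from 239 to 10.3 RPKM (-5.12 ± 1.16, adjusted p = 0.00642), as did the epoxygenase gene Cyp2j5 (-4.52 ± 1.07) and the major urinary protein gene Mup13 (-4.43 ± 0.75). On days 6 to 8, in 3 livers, Mup13 (-5.28 ± 0.75, adjusted p = 0.00056) and Mup1 (-5.23 ± 0.77, adjusted p = 0.00061) fell. On days 10 to 13, in 4 livers, Mup7 (-4.03 ± 0.60, adjusted p = 0.00107), Mup11 (-4.01 ± 0.75), Mup14 (-3.87 ± 0.71) and Mup1 (-3.87 ± 0.73) were low. Oxtr averaged 2.09 RPKM on days 10 to 13 and was listed at 0 in 1 of 2 early libraries. Hcfc1 differed by 0.41 ± 0.24, 0.21 ± 0.24 and 0.26 ± 0.23 and missed the threshold after centring (adjusted p = 0.247, 0.583 and 0.464).

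In Het livers, macrophage genes had 11, 28 and 34 of 35 up in the 3 windows and 0 down (24, 32 and 34 adjusted over the list alone), with Clec4f, a Kupffer cell lectin gene, at 1.99 ± 0.32 on days 10 to 13 (camera adjusted p = 2.26e-08, adjusted p = 0.405 with an estimated correlation). Mitosis genes had 7, 22 and 28 of 29 up (20, 28 and 29 adjusted over the list alone), with Mki67 at 3.03 ± 0.51 on days 10 to 13 (camera adjusted p = 2.37e-07, adjusted p = 0.405 with an estimated correlation). On days 10 to 13, stellate and matrix genes had 25 of 39 up (31 adjusted over the list alone), with Thbs1 at 2.51 ± 0.25 (camera adjusted p = 5.65e-06, adjusted p = 0.356 with an estimated correlation). Of 30 p53 targets, 13 rose then (14 adjusted over the list alone), with Phlda3 from 0.374 to 6.31 RPKM (3.59 ± 0.46) and Eda2r, a TNF receptor family gene, at 4.04 ± 0.56 (camera adjusted p = 0.0118, adjusted p = 0.49 with an estimated correlation). P450 and conjugation genes had 5, 5 and 3 of 27 down and 0 up (6, 5 and 2 down adjusted over the list alone, with 1 up on days 3 to 5), with Cyp2c54 at -1.88 ± 0.26 on days 10 to 13 (camera adjusted p = 7.82e-18, adjusted p = 0.0327 with an estimated correlation). Oxidative phosphorylation genes had 0 of 54 up or down by limma on days 10 to 13 over all genes (camera adjusted p = 1.34e-05, adjusted p = 0.49 with an estimated correlation). The numbers of genes passing were 8675, 10129 and 8437 of 11919, nearly all higher, with the median gene up by 0.64, 0.78 and 0.60. After centring 417 were higher and 229 lower on days 3 to 5, 1137 and 434 on days 6 to 8, and 1605 and 1017 on days 10 to 13. Passing on both scales were 417 up and 63 down, 1137 up and 53 down, and 1605 up and 60 down. A straight line in day over the 12 livers called 2002 genes.

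The difference between the change in Het females and the change in KO males, each from days 0 to 1, asks where the changes differ, though sex and genotype differ together and changes seen in WT males enter too. Mmachc differed on days 6 to 8 by 4.80 ± 0.44 (adjusted p = 2.0e-09), and by 4.41 (adjusted p = 2.76e-08) on days 10 to 13, a value chosen after it was seen. For Ndufa3 these values were 3.15 ± 0.30 and 3.38 ± 0.30, with 112 RPKM in Het and 15.8 in KO livers on days 10 to 13. Atp5d differed by 2.12 ± 0.27 and 3.19 ± 0.27, and Mrpl24 by 2.32 ± 0.25 and 2.64 ± 0.25. Of 54 oxidative phosphorylation genes, 5 rose in Het relative to KO and 0 fell on days 6 to 8 (4 adjusted over the list alone; camera adjusted p = 9.04e-04, adjusted p = 0.775 with an estimated correlation). Female-biased genes had 13 of 19 down and 0 up on days 6 to 8 (16 down adjusted over the list alone), a median of -5.39 and Cyp2a4 at -3.71 ± 0.58 (camera adjusted p = 8.03e-17, adjusted p = 0.00215 with an estimated correlation). In WT males over time 12 of 16 of that list were higher, and in KO against WT males of days 6 to 9 6 of 16 fell. Cyp2b9, of that list, went from 295 to 438 RPKM in Het and from 0.0495 to 52.0 RPKM in KO livers, where it was listed at 0 in 2 of 4 early libraries. Values at the table's minimum enter the list's median, whose size was not checked with 0.1 RPKM added. On days 10 to 13 amino acid genes had 11 of 29 up and 0 down (10 up adjusted over the list alone), a median of 1.30 and Bhmt at 3.38 ± 0.36 (camera adjusted p = 3.27e-11, adjusted p = 0.51 with an estimated correlation).

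On days 10 to 13, of 30 p53 targets, 19 were down in Het relative to KO livers and 0 up (20 down adjusted over the list alone), with Bax at -1.30 ± 0.23 (camera adjusted p = 7.73e-04, adjusted p = 0.698 with an estimated correlation). NRF2 genes had 17 of 32 down and 0 up, with Srxn1 at -3.11 ± 0.31 (camera adjusted p = 3.26e-05, adjusted p = 0.585 with an estimated correlation). Duct cell genes had 12 of 23 down and 0 up, with Krt8 at -2.25 ± 0.24 (camera adjusted p = 0.00454, adjusted p = 0.741 with an estimated correlation). On days 6 to 8, 1592 of 12380 genes passed, 1165 higher and 427 lower. After centring 1287 were higher and 1338 lower, and 1046 rose and 426 fell in both. The count was 929 without the Het liver of day 1. On days 10 to 13, 6607 passed, 797 higher and 5810 lower. After centring 2494 were higher and 2480 lower, and 797 rose and 2480 fell in both. Across genes, which are not independent replicates, the Het change on days 10 to 13 had Pearson's r of 0.547 and Spearman's rho of 0.58 with that of KO males, and 0.606 and 0.776 with that of WT males.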

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

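The slope of the scaling totals and the day 0 value of Alb were tests chosen only after the result was seen, as was the fit after centring each library.

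Direct tests of a difference between time points or between Het and KO livers singled out the following results. The KO-WT difference changed for 7449 genes from days 3 to 5 to days 10 to 14 (6809 after centring), and for 2436 genes from day 0 to days 6 to 9 (3749 after centring, 1362 higher and 1003 lower on both scales). The latter count was 1407 without KO day 0 replicate 2. The change in Het females differed from the change in KO males for 1592 genes on days 6 to 8 (2625 after centring, 1046 higher and 426 lower on both scales), a count of 929 without the Het liver of day 1, and for 6607 genes on days 10 to 13 (4974 after centring). From days 3 to 5 to days 10 to 14, the KO-WT difference of mitosis genes moved by a median of 2.62 and that of cholesterol synthesis genes by -1.5. Female-biased genes changed in Het relative to KO livers by a median of -5.39 on days 6 to 8, and amino acid catabolism genes by 1.3 on days 10 to 13. The female-biased list holds Cyp2b9, which was listed at 0 in some early KO libraries. The size of its median may depend on the constant added before the logarithm, and it was not recomputed with 0.1 RPKM added. Ndufa3 differed by 3.15 on days 6 to 8 and Mmachc by 4.41 on days 10 to 13.

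Swapping genotype labels within days gave other splits of the same libraries. On days 1 to 2 the real labels called 2253 genes and the highest other split 23, and the 18 splits, of which 1 reached the real count, are too few for a share under 0.05. On days 3 to 5, 1 of 100 splits drawn from 108, the real one, reached 6971 genes and the highest other called 4765. On days 6 to 9 it was 1 of 100 drawn from 648, with 7657 genes against 6606. Both shares are under 0.05 and argue against chance for these counts, without excluding it. Some of these splits only turn the sign of whole days. For days 10 to 14 the real labels called the most genes of 48 splits, 10122 against 9832 in the highest other. Most of these days have 1 library per genotype, where a swap only turns the sign of that day's difference. The count for days 10 to 14 therefore tests whether differences keep their sign across days, and cannot exclude chance. Among splits that part as many replicate pairs as the real one, the highest others called 4765, 5860 and 9671 genes. For the change from days 3 to 5 to days 10 to 14, 12 of 100 splits called as many genes as the real 7449, the highest 9596, so chance cannot be excluded by this count. Of the 11 others, 7 set the labels of one window against those of the other, which turns a shared KO-WT difference into a change, and the highest of those that did not called 9285. After centring, 3 of the 100 splits reached the real 6809 genes.

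The median gene was higher in KO than in WT livers on days 10 to 14 by 0.85 as deposited. With totals that leave out the 100 most abundant genes, which take 19.1 to 43.9% of reads, the difference was 0.11, against 0.39 with plain totals, so a few abundant genes taking fewer of the reads may account for part of it. The deposited scaling may add to it. Over 63 libraries the log2 scale total had a slope of 1.46 ± 0.05 on the median log2 value after scaling to totals. A change in total RNA per cell with genotype stays open and was not tested.

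Alb was far lower in KO than in WT livers on days 3 to 5 (-4.17 ± 0.34). The other 34 secreted protein genes had a median of 0.06 (SE 0.13, SD 0.59, both over genes and not mice). That median argues against a loss of hepatocyte RNA as a whole as the cause of the low Alb. It is relative to the median gene, so a loss shared by most genes would not show in it and stays open. In libraries whose Alb share was out of step, at most 30% of the 20 genes named from days 3 to 5, Alb among them, lay on the side of the other genotype, which argues against wrong labels. On day 0 Alb differed by -0.89 ± 0.60, with 3.42 and 3.48% of reads in KO and 6.85 and 5.54% in WT livers. That value argues against a difference before tamoxifen as large as on days 3 to 5. A smaller one stays open. Alb is the gene whose promoter drives Cre here, and an effect of that transgene was not tested. Het livers carry the same Cre with 1 intact Hcfc1 allele, and 7 of 12 had an Alb share under 1%, the lowest 0.613%.

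Markers of duct cells, stellate cells and macrophages were higher in KO livers on days 10 to 14, and those of 2 other cell types near 0, with medians of 2.12 (SE 0.33) for duct cells, 1.19 (SE 0.13) for stellate cells and matrix, 0.73 (SE 0.24) for macrophages, 0.14 (SE 0.09) for endothelial cells and -0.03 (SE 0.18) for T, B and NK cells. A lower share of hepatocyte RNA would raise all 5 alike, and the gap between the highest and the lowest, 2.15 (SE 0.38), argues against it as the whole cause. These SEs are over the genes of a list, taken as independent, and do not measure spread between mice. On each of days 10 to 14 the duct cell median lay above that of T, B and NK cells. Duct cell genes such as Krt8, at 79.5 RPKM in WT livers, are read in the whole organ, so their source among cells was not tested. A change in the types that rose, or in hepatocytes themselves, stays open.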

How the results depend on the processing

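Centring, scaling to totals, 0.1 RPKM added before log2, days 7 and 9 alone, the replicate block with centring, and centred list tests were alternatives chosen after seeing the data. The planned change of pseudocount was not run, since the deposited values are log2 already. Of the counts of genes, 14 stayed within 1.5 times under 0.1 RPKM added, 14 without the variance trend, 8 with batch as a covariate and 3 with shorter windows. Named genes kept direction and side of the threshold in 1152 cases with 0.1 RPKM added (21 lost the call), 1154 with centring, 1159 with total scaling, 1154 without the filter, 1061 with quantile normalization (113 lost it) and 1001 with any 1 library left out (164 lost it). With the replicate block 675 kept and 57 lost it, with the block and centring 651 and 81, and with the libraries of a window alone 475 and 26. Members of lists entered these counts only if they had passed after centring, so their agreement with centring was fixed beforehand. Depth limits genes near the floor, as 1 read on 2000 bases is 0.0097 to 0.036 RPKM. For the values below the cause was not tested.

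Centring gave 3749 genes for the change from day 0 to days 6 to 9, 5997 for WT males over time, 646, 1571 and 2622 for Het females on days 3 to 5, 6 to 8 and 10 to 13, and 2625 for Het minus KO on days 6 to 8. Total scaling gave 14 on day 0, 6107 for WT males, 2182, 3611 and 3391 for Het females and 2496 for Het minus KO on days 6 to 8. Quantile normalization gave 1435 on days 1 to 2, 3978 for the change from day 0, 5306 for WT males, 170, 754 and 1562 for Het females and 2704 for Het minus KO on days 6 to 8. A straight line in day called 2002 genes in place of each Het window. Without the filter, 23 genes passed on day 0. The libraries of days 1 to 2 alone gave 1230. With replicate pairs as blocks, limma called 0 genes on day 0, where 357 had an unadjusted p under 0.05, and 1463 on days 1 to 2; with centring as well, it called 1 and 1174.

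Leaving out 1 library gave 4 genes (without KO day 0 replicate 2) to 44 (without WT day 0 replicate 1) on day 0. On days 1 to 2 it gave 886 (without KO day 1 replicate 2) to 2946 (without KO day 1 replicate 1), with 1061 without WT day 1 replicate 2, 1288 and 1334 without WT day 2 replicates 1 and 2 and 1094 without KO day 2 replicate 2. For the change from day 0 it gave 1407 (without KO day 0 replicate 2) to 2960, and for Het minus KO on days 6 to 8 929 (without Het day 1) to 2093. The other 155 of 164 such fits stayed within 1.5 times.

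Lists were compared on days 10 to 14. With an estimated correlation the call was lost for bile acid and gluconeogenesis genes (0.246), cholesterol synthesis and amino acid catabolism (0.259), female-biased genes (0.263), NRF2, secreted proteins and p53 targets (0.56), duct cells, lipogenesis, P450s, fatty acid oxidation, lipid droplets, male-biased genes and stellate cells (0.588), the unfolded protein response (0.692), macrophages (0.836) and oxidative phosphorylation (0.837). Centring ended the call for P450s (0.149), female-biased (0.315), lipid droplet (0.498) and male-biased genes (0.131), and gave one for mitosis (0.0309) and fetal genes (0.00104). Quantile normalization ended it for P450s (0.458), female-biased genes (0.238), secreted proteins (0.0816), lipid droplets (0.538) and male-biased genes (0.168), and gave one for fetal genes (0.00199). Without the filter the HCF-1 list (0.0499) and fetal genes (0.0474) passed and oxidative phosphorylation (0.0947) did not.

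The rotation test fry does not compare a list with other genes. It was run on the deposited values, where the median gene was higher in KO livers by 0.85. That shift enters its calls and directions, so a list that only follows the median gene can be called. It gave calls for DNA replication (9.12e-07), mitosis (1.14e-05), HCF-1 partners (5.29e-09), and cytosolic (1.74e-07) and mitochondrial ribosome (7.87e-09). It also called endothelial (8.87e-06), fetal (2.46e-13) and immediate early genes (2.46e-10), and not lipogenesis (0.614). Its direction was opposite to camera's for T, B and NK cells (0.000147), acute phase (0.012), clock (2.15e-07), P450s (0.00321), erythrocytes (1.74e-07), fatty acid oxidation and female-biased genes (0.441), secreted proteins (0.119), lipid droplets (0.000115), male-biased genes (0.447), neutrophils (0.000109) and oxidative phosphorylation (0.022).

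Single genes changed sign in few settings. Ccl7 had 2.22 for the change from day 0 with 0.1 RPKM added. With 1 library left out, Clcf1 had 0.29 for that change, Snord52 -0.03 and -0.14 and Mir3082 -0.99 for Het minus KO, Hcfc1 -0.04 on day 0, -0.05 in WT males over time and -0.13 and -0.09 in Het females of days 6 to 8 and 10 to 13, and Srebf2 -0.07 in WT males over time.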

Other observations

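The test after centring each library, which counts of genes that rose, fell, were higher or were lower in this part also require, was chosen only after seeing the data.

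In WT males over time, with genes past limma's F test over any window counted by their direction on days 10 to 14, 11 of 12 neutrophil genes were higher and 0 lower (10 higher adjusted over the list alone), with Ngp, a granule protein gene, at 2.64 RPKM on days 10 to 14 against 0.0102 on day 0, where it was listed at 0 in 1 of 2 libraries (camera adjusted p = 0.00539, adjusted p = 0.434 with an estimated correlation). All 3 erythrocyte genes were lower (1 adjusted over the list alone), including Alas2, the heme synthesis enzyme gene of red cell precursors (-2.57 ± 0.28; camera adjusted p = 2.3e-08, adjusted p = 0.000215 with an estimated correlation). Endothelial genes had 24 of 28 up and 0 down (14 up adjusted over the list alone), with Lyve1 at 1.54 ± 0.35 (camera adjusted p = 0.0288, adjusted p = 0.713 with an estimated correlation). Stellate and matrix genes had 29 of 41 up and 0 down (25 up adjusted over the list alone), with Sparc at 1.09 ± 0.21 (camera adjusted p = 5.91e-05, adjusted p = 0.51 with an estimated correlation).

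In Het females of days 10 to 13, 12 of 14 neutrophil genes rose and 0 fell, also adjusted over the list alone, with Ngp at 4.75 ± 0.62 and Chil3 at 2.95 ± 0.52 (camera adjusted p = 0.0353, adjusted p = 0.422 with an estimated correlation). T, B and NK cell genes had 12 of 21 up and 0 down (18 up adjusted over the list alone), including the B cell receptor gene Cd79a (2.35 ± 0.37) and Ms4a1, which encodes CD20 (2.13 ± 0.38), with camera adjusted p = 0.00354 and adjusted p = 0.437 with an estimated correlation. On days 6 to 8, acute phase genes had 3 of 30 down and 0 up (2 down adjusted over the list alone), with the hepcidin gene Hamp2 at -4.77 ± 0.90 and the metallothionein gene Mt1 at -2.39 ± 0.43 (camera adjusted p = 3.13e-35, adjusted p = 0.0482 with an estimated correlation). In KO against WT males of days 3 to 5, male-biased genes split 6 up and 7 down of 18, also adjusted over the list alone, with Cyp4a12b at 3.27 ± 0.46 and Serpina4-ps1 at -3.31 ± 0.40 (camera adjusted p = 0.0446, adjusted p = 0.994 with an estimated correlation). Cyp4a12b fell in WT males over time (-5.74 ± 0.67), so its higher value need not be a rise within KO livers.

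Alb took 3.42 and 3.48% of reads in the KO livers of day 0. Of the 24 KO livers of days 1 to 14, those above 1% were day 6 replicate 2 (6.02%), both of day 8 (5.55 and 6.23%) and the unnumbered library of day 14 (2.28%). Among 12 Het livers the share spanned 0.613 to 6.9%, with 7 under 1% and 5.97% on day 0, 3.21% on day 1, 4.29% on day 3, 6.9% on day 10 and 6.54% on day 12.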
